A study of Mus musculus with 2 samples.

How the data were processed

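The series holds 2 droplet libraries of sorted macrophages (positive for CD45, CD11b and CD64) from mouse hearts 3 days after myocardial infarction, 1 from WT and 1 from CD40 KO mice. Replicate names carry no pairing, and the allele and the number of mice per library are not given in the sources used here. Libraries were made with the Chromium 3′ v3 kit, per the labels' protocols. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 7.0.1 per the file headers. The submitters' processing notes name Cell Ranger and STAR without versions and the mouse build mm10. Whether reads in introns were counted is not stated. Each matrix had 32285 genes. Positions came from a copy of GENCODE vM21, which need not be the annotation the authors used.

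Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 8094 in WT and 7930 in the library labelled CD40 KO. In WT 1547 barcodes missed the UMI or gene minimum and 1860 the mitochondrial limit, against 2 and 216 in the library labelled CD40 KO. The shallowest deposited barcode had 500 UMIs in WT and 1618 in the other library. Scrublet scores, as run in scanpy 1.11.5, were computed per library. Its own threshold marked 48 and 0 barcodes and was not used. The barcodes with the highest scores were removed instead, at a fixed rate of 0.8% per 1000 barcodes, which marked 903 and 531. After removal 7249 and 7404 barcodes remained. Counts were scaled to 10000 per barcode and log transformed, 2000 variable genes were chosen without *Cd40*, sex-linked, mitochondrial, ribosomal protein and haemoglobin genes, and 30 principal components and 15 neighbours were used for Leiden clustering of both libraries together at resolution 0.6. This gave 15 clusters. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

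Clusters were named from marker lists fixed before the data were examined, by their leading genes. Clusters 1, 2, 3, 6 and 8 form the monocyte/macrophage-like class, with 5126 barcodes in WT and 2326 in the library labelled CD40 KO. The limits of the naming rule were set after the clusters had been seen, and they kept 4 clusters without a name. Cluster 13 drew at least 95% of its barcodes from 1 library with library sizes made equal. Cluster 7, with 885 and 176 barcodes, had as many leading markers of neutrophils as of macrophages. Cluster 4, with 133 and 62, was shallow with no marker among its leading genes, and cluster 9, with 75 and 74, had fewer than 3 detected markers. Marker lists of T and NK cells were merged after cluster 12 had first come out unnamed, and those of dendritic types were merged likewise. In the other clusterings the same rule gave unstable names: large clusters came out unnamed at resolutions 0.3 and 1.0, and the cluster with neutrophil transcripts passed as macrophage-like under 2 of the filter alternatives. The alternatives were therefore named by the main cluster that held most of their barcodes, so their shares are not independent of the main naming.

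Raw UMIs of the class were summed per library and scaled to CPM. Ratios are CPM of the library labelled CD40 KO over WT, with exact conditional (Clopper-Pearson) 95% intervals. CPM values have exact Poisson intervals and shares exact binomial (Clopper-Pearson) intervals. Beside a count of 0, the share that 3 barcodes would make is given as its limit. With 1 library per group intervals and limits cover counting error only, and no test between groups was made. A gene was measured at a mean of at least 10 CPM and counted by size, at 1.5-fold, and a list member at 1.3-fold. For each of 33 fixed gene lists the median ratio was set against 10000 random lists matched on expression in 20 bins, which describes these libraries and is not a test. Ratios were repeated within clusters 1 and 3, the clusters of the class with at least 200 barcodes in both libraries. For list medians the floor of 10 CPM was applied again within each cluster. Such a median can therefore cover other members than the median of the class. Shares of barcodes with a UMI were also taken after thinning each barcode to 3000 UMIs, which left out 154 and 57 barcodes of the class.

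Named genes followed a rule fixed before the data were examined: *Cd40*; the 12 highest and 12 lowest ratios at a mean of at least 50 CPM, without sex-linked, haemoglobin, immunoglobulin, ribosomal protein, mitochondrial and unnamed genes; the 2 highest and 2 lowest members of each list; and a fixed set of efferocytosis and macrophage genes. This gave 154 genes, of which the text prints a part, and 1 was left out on purpose and is not reported here. *S100a8*, *S100a9*, and the leading genes of clusters were named after their values were seen.

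Settings fixed before the data were examined changed scaling, cell weights, cluster weights, barcode filters, doublet removal, depth, the CPM and fold limits, the clustering resolution and the treatment of library differences. Alternatives added after the data were seen put cluster 13 or cluster 7 into the class, used all barcodes that passed the filters, subtracted a background profile, or clustered without 939 genes at least 1.5-fold apart, which are all such genes except the ribosomal protein and mitochondrial genes already left out of clustering. The background profile was that of cluster 13, and its share of the class of the library labelled CD40 KO, 6.31% of UMIs, was set from 6 fibroblast genes. This assumes that cluster 13 has the profile of free RNA, and WT had no like correction. The fold rule and the intervals were tested on simulated counts with 200 planted genes among 7564. All planted genes were recovered, 0 of 7364 unchanged genes passed the fold limit, and the intervals held the true ratio for 95.7% of genes. Both simulated libraries were Poisson draws from 1 pooled profile, without cells, library effects or free RNA. At this depth counting error alone can hardly reach 1.5-fold, so the test checks the arithmetic and not the genes counted in the real libraries. Planted genes were drawn from at least 2 times the CPM floor, after a first version lost genes to that floor, so recovery near the floor was not covered.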

Results

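Single-cell RNA sequencing measured macrophages of mouse hearts 3 days after myocardial infarction. The cells were sorted from the infarct and border zones as positive for CD45, CD11b and CD64. There were 2 groups, wild type (WT) and CD40 knockout (KO), with 1 library in each. The number of mice behind a library is not given in the sources used here. The WT library held 10624 cell barcodes and 139343516 UMIs (molecules counted once each), with a median of 9354 UMIs and 2970 genes per barcode. The library labelled CD40 KO held 8146 barcodes and 90057108 UMIs, with a median of 5347 UMIs and 2036 genes. After filters and doublet removal 7249 and 7404 barcodes remained. With 1 library per group there was no replicate check and no test between groups: intervals are 95% exact intervals and cover counting error only, and every direction given is between the WT library and the library labelled CD40 KO.

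*Cd40*, the targeted gene, encodes a receptor of the TNF receptor family. Its transcript was present at similar levels in both libraries. In the monocyte/macrophage-like class *Cd40* (ENSMUSG00000017652) stood at 17.3 CPM (counts scaled to 1000000 UMIs; 16.4 to 18.3) in WT and at 15.5 CPM (14.4 to 16.6) in the library labelled CD40 KO, a log2 ratio of −0.16 (−0.30 to −0.03). Dendritic-like cells held more in both libraries, 38.9 and 37.5 CPM. A UMI of *Cd40* was seen in 19.1% and 21.8% of macrophage-like barcodes at median depths of 11691 and 15509 UMIs, and in 4.97% and 3.97% once each barcode was thinned to 3000 UMIs. In the neutrophil-like cluster, taken as a type that should have little of it, the share was 0.993% and 3.13% at median depths of 2358 and 2965 UMIs. After thinning it was 0 of 71 and 0 of 30 barcodes there, and 3 barcodes, taken as the limit that a count of 0 allows, would be 4.23% and 10.0% with a UMI at that depth. The gene lies on the plus strand of chromosome 2, from 165055627 to 165072948 in GENCODE vM21, and the last exon of its transcript *Cd40*-201 spans 165070722 to 165072948. The assay counts tags near the 3′ end. The deleted part of the allele is not given in the sources used here, so a tag from a 3′ end that the allele keeps checks nothing about the knockout, and the counts do not establish which library came from knockout mice. Over all barcodes that passed the filters the ratio had the other sign, 0.043.

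The comparison of cell types asked what the sort gate held. Monocyte/macrophage-like cells made up 70.7% (69.7 to 71.8) of kept barcodes in WT and 31.4% (30.4 to 32.5) in the library labelled CD40 KO. The gap came with cluster 13, which held 4309 barcodes (58.2%) of the library labelled CD40 KO and 24 (0.331%) of WT and was given no cell type. Without that cluster the macrophage-like share was 70.9% (69.9 to 72.0) and 75.2% (73.6 to 76.7). On the same basis neutrophil-like barcodes were 4.18% and 2.07%, dendritic-like 4.15% and 8.72%, endothelial-like 2.84% and 0.388%, and fibroblast-like 1.80% and 2.81%. B-like barcodes were 0.388% in both, and T-like or NK-like barcodes 0.567% and 0.388%. The shallowest deposited barcode of the library labelled CD40 KO had 1618 UMIs, while WT barcodes were kept from 1000 UMIs. Shares of shallow types, such as neutrophil-like barcodes with a WT median of 2358 UMIs, carry this difference in depth limits.

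**Figure D1:**
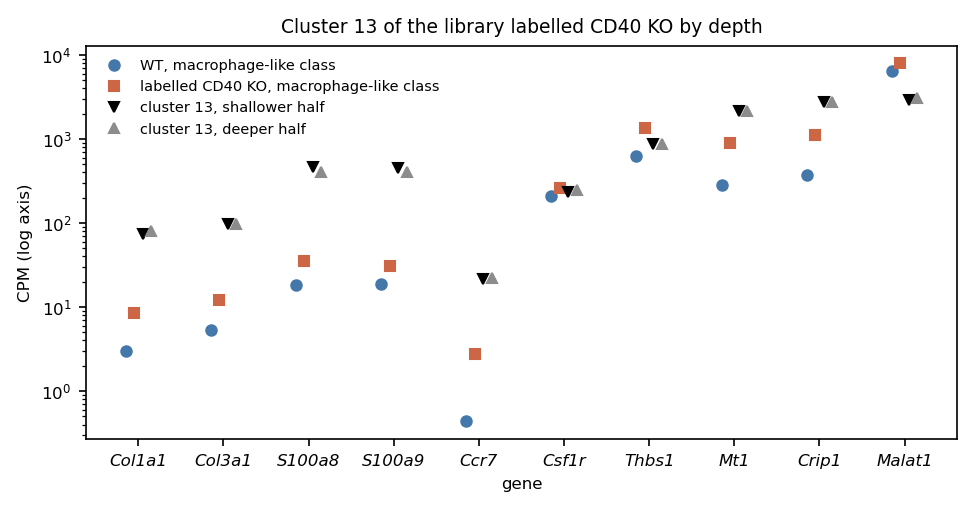
CPM (log axis) of 10 genes in the macrophage-like class of both libraries and in the shallower and deeper barcodes of cluster 13 of the library labelled CD40 KO, split at the median depth. In both parts of cluster 13 the level was alike, for *Col1a1* 73.6 and 80.1 CPM against 2.97 CPM in WT and 8.38 CPM in the class of the library labelled CD40 KO.

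A further group, cluster 7, held macrophage genes such as *Gpnmb* and *Selenop* together with neutrophil genes such as *Hdc*, *G0s2* and *Csf3r*, and was kept apart from the class. It was 14.7% (13.8 to 15.6) of macrophage-like plus cluster 7 barcodes in WT and 7.03% (6.06 to 8.11) in the library labelled CD40 KO. Neutrophil-like barcodes numbered 5.02 and 2.56 per 100 of the same barcodes, counts that carry the difference in depth limits given above.

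**Figure D2:**
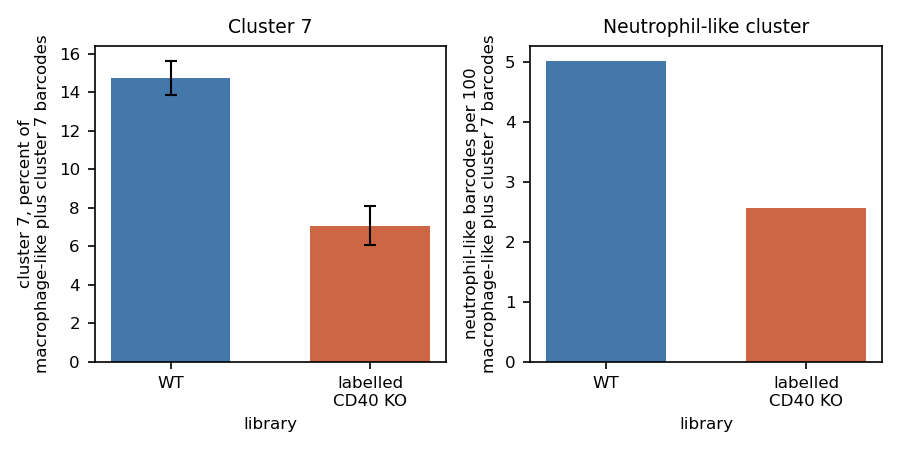
Left, cluster 7 in percent of macrophage-like plus cluster 7 barcodes, with 95% exact binomial intervals for counting error only; right, neutrophil-like barcodes per 100 of the same barcodes. Both were lower in the library labelled CD40 KO, at 7.03% against 14.7% and at 2.56 against 5.02. Kept WT barcodes reached lower depths than any deposited barcode of the other library, which bears on the neutrophil-like counts.

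Within the macrophage-like class the libraries differed most, in percentage points, in clusters 1 and 3. Cluster 1 was led by *Gpnmb*, *Fabp5*, *Lpl*, *Spp1* and *Igf1*, genes of Trem2 or lipid-associated macrophages, and held 52.2% (50.8 to 53.6) of the class in WT against 16.4% (14.9 to 17.9) in the library labelled CD40 KO. Cluster 3 was led by *Met*, *F13a1*, *Plcb1* and *Thbs1*, matched none of the fixed macrophage states, and held 22.4% (21.3 to 23.6) against 60.1% (58.1 to 62.1). The interferon-response cluster 2, led by *Ifit3* and *Rsad2*, held 18.5% and 8.21%. The cycling cluster 6, led by *Top2a* and *Mki67*, held 4.49% and 7.91%, and cluster 8, led by *Scin* and *Saxo1*, held 2.38% and 7.39%. Since the genes that differ between libraries also shape the clusters, cells were clustered again without 939 genes that differed at least 1.5-fold (all such genes except ribosomal protein and mitochondrial genes, which were never used for clustering): cluster 1 then held 41.2% and 20.6% of the class, and cluster 3 52.5% and 64.5%.

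**Figure D3:**
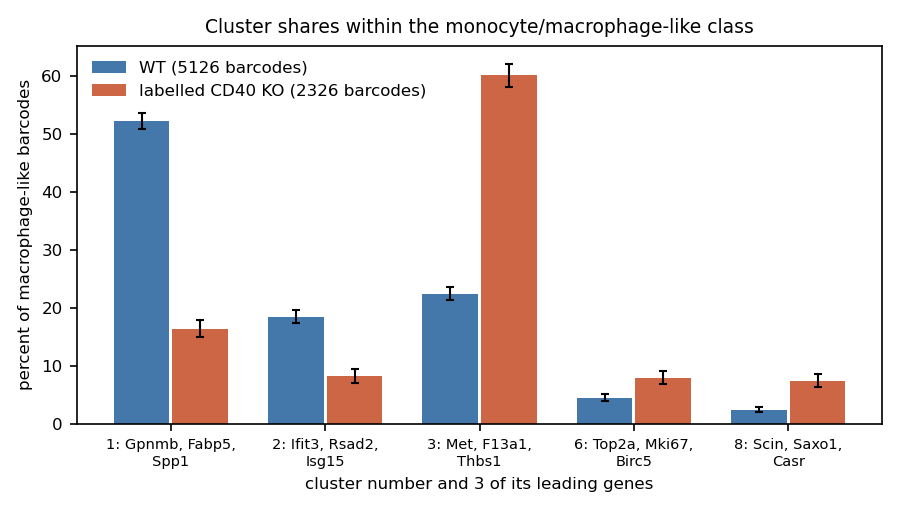
Share of each macrophage-like cluster, in percent of the class, in the WT library (blue) and the library labelled CD40 KO (orange); whiskers are 95% exact binomial intervals for counting error only. Cluster 1 held 52.2% and 16.4%, and cluster 3 held 22.4% and 60.1%.

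Comparing the expression of the whole class, which was mostly cluster 1 in WT and cluster 3 in the library labelled CD40 KO, lipid-handling and lysosomal genes were lower and some inflammatory genes higher in the library labelled CD40 KO. *Fabp5*, a fatty acid binding protein, stood at 7149 CPM in WT and 2073 CPM there (log2 −1.79), and *Spp1*, which encodes osteopontin, at 11045 and 4808 CPM (−1.20). *Ptgs2*, the inducible prostaglandin synthase, stood at 85.7 and 327 CPM (1.93), and *Il1b*, an inflammatory cytokine, at 416 and 1031 CPM (1.31). Of 7579 genes measured, 698 were at least 1.5-fold higher and 268 at least 1.5-fold lower. With median-of-ratios scaling, which moved the median gene by 0.10 on the log2 scale, the counts were 494 and 465, and with cluster shares made equal they were 334 and 139. Ribosomal protein genes accounted for 21 of the higher and 3 of the lower genes.

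Among the genes with the highest ratios were the metallothioneins *Mt2* (2.17) and *Mt1* (1.64), the EGF family ligand *Areg* (2.10), the chemokine *Cxcl3* (1.96), *Plcb1* (1.86), *Ifi27l2a* (1.82), *Abcc4* (1.78), *Jdp2* (1.74), *Vcan* (1.71), *Crip1* (1.56) and *Hist1h1c* (1.53). *Mt1*, *Crip1* and *Ifi27l2a* were also among the leading genes of cluster 13, at 2157, 2783 and 2880 CPM. Once the profile of that cluster was subtracted from the class of the library labelled CD40 KO, their log2 ratios lay between 1.40 and 1.74. At the low end stood *Fabp4* (−2.15), *Grik3* (−1.75), *Arf5* (−1.53), *Syngr1* (−1.49), *Gpnmb* (−1.38), *Lpl* (−1.35), which encodes lipoprotein lipase, *Ctsl* (−1.27), which encodes cathepsin L, *Igf1* (−1.26) and *Cd63* (−1.16). *Ftl1-ps1* (−1.51) is a pseudogene of a ferritin chain, and its reads are hard to separate from those of *Ftl1* (−0.70). *Fabp4* was at 12394 CPM in the endothelial-like cluster of WT, a type that made up 2.83% of kept barcodes in WT and 0.162% in the library labelled CD40 KO and that the CD45 gate should exclude. *Cdh5*, another endothelial gene, stood at 2.10 and 1.47 CPM in the class, and *Fabp4* was also lower within clusters 1 and 3, at −1.20 and −1.57. With cluster shares made equal several of these ratios were smaller by over 1.5-fold: *Areg* 1.36, *Ptgs2* 1.34, *Abcc4* 1.18, *Plcb1* 1.14 and *Vcan* 0.75 at the high end, and *Fabp4* −1.35, *Fabp5* −1.002, *Syngr1* −0.76, *Lpl* −0.62, *Igf1* −0.58 and *Gpnmb* −0.57 at the low end.

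Efferocytosis, the uptake of dead cells, is the process that the series title names. Its fixed list of receptors and bridging proteins had a median log2 ratio of −0.14, below all but 0.765% of 10000 random lists of like expression. The medians of its members' own lower and upper bounds were −0.20 and −0.09, which are not an interval of the list median. Of 29 measured members 4 were at least 1.3-fold higher, 10 at least 1.3-fold lower and 15 in between. The lower members included *Mfge8*, a bridging protein (19.2 and 8.72 CPM, −1.14), *Trem2*, a lipid receptor (649 and 364 CPM, −0.84), *Cd36*, a scavenger receptor (575 and 338 CPM, −0.76), and *Gas6*, a ligand that links dying cells to their receptors (88.4 and 59.6 CPM, −0.57). *Mertk*, a main receptor for dying cells, stood at 60.3 CPM in WT and 47.1 CPM in the library labelled CD40 KO (−0.36, −0.43 to −0.29), short of 1.3-fold. *Thbs1* (624 and 1358 CPM, 1.12) and *Havcr2* (48.0 and 98.3 CPM, 1.04) were higher. *Stab1* (−0.36), *Axl* (−0.22), *Lrp1* (0.16) and *Itgav* (0.13) also differed by less than 1.3-fold. *Timd4* was close to the floor at 0.478 and 0.231 CPM, from 36 and 11 UMIs (−1.05, −2.17 to −0.05), and over all barcodes that passed the filters its ratio had the other sign, 0.16.

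Members of the efferocytosis list differed in how far they held within clusters. The list's median was −0.099 with cluster shares made equal, 0.00 within cluster 1 and −0.11 within cluster 3. *Mertk* (ENSMUSG00000014361, chromosome 2, 128698956 to 128802894) had log2 ratios of 0.03 within cluster 1 and −0.10 within cluster 3, and 0.02 for the class with cluster shares made equal. *Gas6* had 0.14 and −0.12, *Stab1* 0.02 and 0.00, and *Mfge8* −0.36 and 0.17. *Trem2* (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147) remained lower in both, at −0.23 and −0.39, as did *Cd36*, at −0.25 and −0.53. *Thbs1* remained higher, at 0.63 and 0.60, and so did *Havcr2*, at 0.72 and 0.65. The engulfment machinery, genes of actin remodelling around the dying cell, had 4 members higher, 1 lower and 21 in between, with *Dock4* (0.88) and *Vav3* (0.64) highest and *Arpc3* (−0.67) lowest. Phagosome maturation genes had 3 higher, 3 lower and 20 in between, with *Cyba*, an NADPH oxidase subunit, lowest (−0.69). Antiphagocytic and shedding genes had a median of 0.14, with 2 of 10 members higher, *Pecam1* (0.84) and *Adam9* (0.67), 1 lower and 7 in between. Among them *Sirpa*, the receptor for CD47, was lower (−0.56), while *Cd47* (0.10) and *Adam17* (0.00) were nearly level.

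Genes of Trem2 and lipid-associated macrophages were lower in the library labelled CD40 KO. The list's median was −0.84, below all 10000 random lists, with 11 of 15 members lower, 1 higher (*Itgax*, 0.42) and 3 in between. Lysosomal degradation genes had a median of −0.44, also below all random lists, with 21 of 36 members lower and none higher, *Ctsl* and *Gpnmb* lowest. Cholesterol and lipid handling genes had a median of −0.27, with 8 of 18 members lower and 1 higher, *Ppard* (0.38), a lipid-sensing nuclear receptor, while the efflux pump *Abca1* (0.31) was short of 1.3-fold. Within clusters 1 and 3 the medians were −0.29 and −0.36 for the Trem2 list, −0.06 and −0.23 for the lysosomal list, and −0.19 and −0.28 for the lipid list. Cluster 13 of the library labelled CD40 KO also held such genes. After thinning, 84.5% of its barcodes had a UMI of *Trem2*, against 71.9% of the class in WT and 52.1% in that library. For *Fabp5* the shares were 99.6%, 87.5% and 76.3%, and for *Gpnmb* 49.7%, 56.5% and 30.9%. Thinning left out 1949 of the 4309 barcodes of cluster 13. Such shares also depend on how evenly a transcript is spread over barcodes, so they do not rank levels. *Spp1* had a UMI in 100% of cluster 13 and 92.5% of the class in WT, yet stood at 5474 and 11045 CPM there.

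The Ly6c monocyte and proinflammatory lists had higher medians in the library labelled CD40 KO, while those of chemokines and the interferon gamma response lay within the range of random lists. The Ly6c monocyte list had a median of 0.71, with 10 of 14 members higher, among them *Vcan* (1.71) and *Thbs1* (1.12), and 1 lower, *Lyz2* (−0.38). With cluster shares made equal that median was −0.01, and within clusters 1 and 3 it was −0.20 and 0.05. The list of proinflammatory cytokines and mediators had a median of 0.69, with 12 of 16 members higher, among them *Ptgs2* (1.93) and *Il1b* (1.31), and 1 lower, *Tnf* (−0.49). That median was 0.31 with cluster shares made equal, and 0.38 and 0.12 within clusters 1 and 3. *Il1b* was 0.61 with cluster shares made equal, and *Tnf* was lower within both clusters, at −0.69 and −0.81. The same list holds *S100a8* (0.94) and *S100a9* (0.73), abundant neutrophil genes that stood at 424 and 419 CPM in cluster 13, and once its profile was subtracted both were below 0, *S100a9* at −1.93. The list median was then 0.60. WT had no such subtraction, so these values set a corrected library against an uncorrected one. Chemokines had a median of 0.08, at percentile 52.87 of the random lists, with 7 of 18 members higher and 3 lower. Interferon gamma response genes had a median of 0.04, at percentile 27.76, and −0.47 and −0.37 within clusters 1 and 3. Dissociation and immediate early genes, which respond to handling, had a median of −0.20 (−0.26 and −0.39 within clusters 1 and 3), with 8 of 19 members lower, among them *Klf2* (−0.98) and *Egr1* (−0.69), and 1 higher, *Nr4a1* (0.70). Among extracellular proteases *Mmp9* was highest, at 7.42 and 37.7 CPM (2.34). Its ratio was smaller within clusters 1 and 3, at 0.87 and 1.17. It was 0.52 when cluster 7, whose cells held neutrophil transcripts, was added to the class.

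Over the whole class, genes of CD40 signalling were mostly higher, not lower, in the library labelled CD40 KO. The list's median was 0.40, at percentile 99.97 of the random lists, with 11 of 20 members higher and none lower. *Traf1* (1.14, and 0.53 with cluster shares made equal), an adaptor of TNF receptors, and *Nfkbie* (1.03), an NF-κB inhibitor, were highest. Within clusters 1 and 3 *Traf1* was 0.60 and 0.44, and *Nfkbie* 0.87 and 0.56. *Nfkbia* (−0.37) was lowest, short of 1.3-fold in the class but past it within clusters 1 and 3, at −0.49 and −0.66. Within clusters 1 and 3 the list medians were 0.14 and 0.18. Costimulation genes had a median of 0.56, with 4 of 7 members higher, among them *Cd80* (1.21) and *Cd83* (0.72). That median was 0.089 with cluster shares made equal, and −0.02 and 0.28 within clusters 1 and 3.

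Among other gene groups, cell cycle genes were higher in the library labelled CD40 KO. S phase genes had a median of 0.48, with 11 of 18 higher, among them *Hells* (0.97) and *Mcm5* (0.90), and G2 and M phase genes had a median of 0.57, with 12 of 16 higher, among them *Kif11* (0.91). Both medians stood at percentile 99.99 of the random lists. With cluster shares made equal they were 0.36 for S phase and 0.21 for G2 and M phase, and within clusters 1 and 3 they were 0.30 and 0.79 for S phase and 0.20 and 0.47 for G2 and M phase. Hypoxia and glycolysis genes had a median of 0.30, with 12 of 27 higher, among them *Vegfa* (1.43) and the lactate exporter *Slc16a3* (1.39), and 1 lower, *Pgam1* (−0.58). Eicosanoid genes had a median of 0.45, which was 0.28 with cluster shares made equal, and 0.39 and 0.14 within clusters 1 and 3. Type I interferon genes had a median of 0.29, with 11 of 25 higher and 2 lower, *Ifit3* (−0.65) and *Bst2* (−0.44), and the median was 0.07 and 0.00 within clusters 1 and 3. Lower groups were the unfolded protein response, with a median of −0.33 and *Sdf2l1* (−1.04) and *Pdia6* (−0.96) lowest, and MHC class II presentation, with a median of −0.34 and *Ctss* (−0.81) and *H2-Aa* (−0.63) lowest. The MHC class II median was 0.22 over all barcodes that passed the filters. The reparative and alternative activation list had a median of 0.18, with 8 of 27 members higher, *Areg* (2.10) highest, and 2 lower, *Igf1* (−1.26) and *Spp1* (−1.20). Its members *Il10* (0.20), *Tgfb1* (0.35) and *Arg1* (0.10) differed by less than 1.3-fold.

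**Figure D4:**
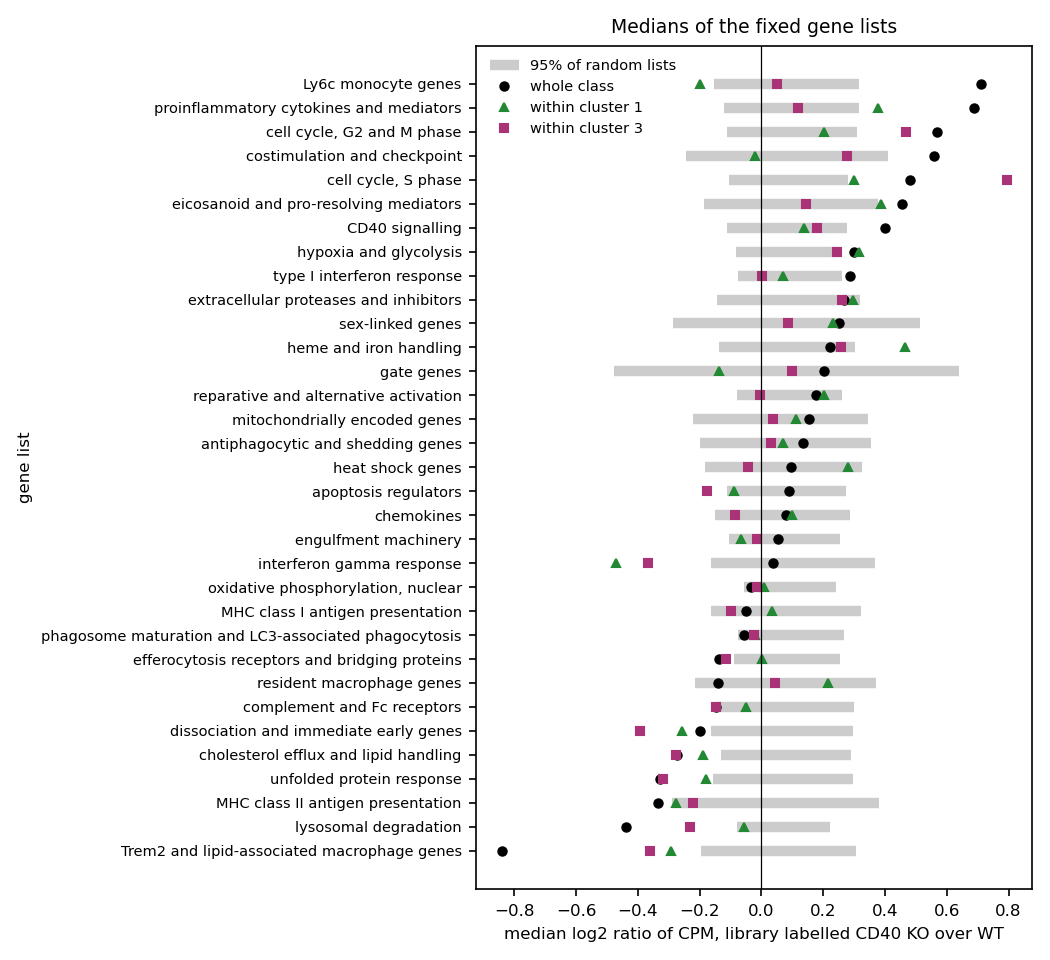
Median log2 ratio of each fixed gene list, library labelled CD40 KO over WT, for the whole class (circles), within cluster 1 (triangles) and within cluster 3 (squares); grey bars hold 95% of random lists matched on expression. The Trem2 list lies at −0.84 for the class and at −0.29 and −0.36 within clusters 1 and 3, and the Ly6c list at 0.71, −0.20 and 0.05. Members were chosen by their level in the class or in the cluster, so the 3 medians of a list can cover different genes.

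Within clusters, fewer genes were past 1.5-fold. Of the 698 higher genes, 679 were also higher within cluster 1 and 690 within cluster 3, and 272 and 293 of them by at least 1.5-fold. Of the 268 lower genes, 265 were also lower in each, 90 and 127 by at least 1.5-fold. The same barcodes are part of the class sums, so a shared direction is partly built in; of all measured genes 57.8% and 54.4% were higher within clusters 1 and 3. *Arf5* (−1.59 and −1.55), *Mt2* (2.24 and 2.39) and *Hist1h1c* (1.48 and 1.55) differed as much within clusters as in the class, while *Gpnmb* (−0.29 and −1.03) and *Vcan* (0.75 and 0.68) differed less.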

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

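The tests of cluster 13 were chosen after the result was seen, and the last of them replaced a weaker first version, in which the markers of all 6 other types were higher by any amount, 1 of them by 1.03-fold only. In the library labelled CD40 KO, cluster 13 held 4309 barcodes, 58.2% of those kept, that the main comparisons of expression left out, against 24 in WT. Its barcodes had a median of 3205 UMIs (1618 to 77454), with *Mt1* and *Crip1* high at 2157 and 2783 CPM and *Malat1*, a nuclear transcript, low at 3016 CPM against 7956 in the class.

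Fibroblast markers (8 genes, none at 10 CPM in the WT class) were 9.26 times the level of the class in the same library. Markers of 3 of 6 other cell types were at least 1.5-fold higher, just the number that the rule, set afterwards, asked for. These values argue against macrophages read at low depth, or a macrophage state of the genotype, with the same share of free RNA as the class. An equal amount of free RNA would be a larger share of a shallow barcode. Shallow macrophages that hold it are therefore not excluded. *Col1a1* and *Col3a1* stood at 78.2 and 96.4 CPM, *S100a8* and *S100a9* at 424 and 419 CPM, although the CD45 and CD64 gates would remove fibroblasts and most neutrophils. A candidate explanation is free RNA filling droplets without an intact cell: after thinning, the median variance over mean of its genes was 1.02, near the 1 of random sampling from 1 shared profile, against 1.13 to 1.26 in macrophage-like clusters of that library. A point that leaves this open is the amount, since the class held an estimated 1295 background UMIs per barcode while cluster 13 held 4078 on average. Damaged cells with such RNA were not tested separately.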

How the results depend on the processing

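Alternatives that put cluster 13 or 7 into the class, used all passing barcodes, subtracted background or left out genes from clustering were chosen after the data were seen; the others were planned. Where a value moved, the cause was not tested, except that fold and CPM limits change counts by construction. The *Cd40* log2 ratio was −0.37 thinned to 3000 UMIs, −0.0047 with cluster 13 added and 0.043, reversed, over all passing barcodes. Genes higher in the library labelled CD40 KO numbered 334 with cluster shares made equal, 425 over all passing barcodes, 415 at 30 CPM, 6758 with no floor beyond 1 UMI, 1573 at 1.3-fold and 194 at 2-fold. Lower genes numbered 465 with median-of-ratios scaling, 139 with cluster shares made equal, 174 at 30 CPM, 1232 with no floor beyond 1 UMI, 798 at 1.3-fold and 33 at 2-fold. The efferocytosis median was −0.24 with median-of-ratios scaling, −0.077 as a mean over barcodes and −0.21 with cluster 7, and it was below 0 in every alternative run. Among lists and named genes at least 1.3-fold apart in the main setting, reversed were the Ly6c monocyte list (−0.0060) and *Mmp12* (0.13) with cluster shares made equal, *Il1r2* (−0.13) with cluster 7 added, and *Acod1* (−0.17), *Pecam1* (−0.75) and *Timd4* (0.16) over all passing barcodes. Lists and named genes less than 1.3-fold apart were not counted as reversed, though some changed sign. Examples are MHC class II (0.22) over all passing barcodes, and resident macrophage genes (0.15) and the gene *Mertk* with cluster shares made equal. The macrophage-like share, in points, differed by −35.7 at 20% mitochondrial UMIs and −36.3 without doublet removal. The cluster 1 share differed by −28.8 at resolution 1.0, −28.0 at 2000 UMIs, −30.2 without doublet removal and −20.6 clustered without the differing genes. The cluster 3 share differed by 26.4 and 33.2 at resolutions 0.3 and 1.0, 32.7 with genes centred per library, 34.0 at 20% mitochondrial UMIs, 24.9 at 2000 UMIs, 24.2 without doublet removal and 12.02 clustered without the differing genes. These shares were named from the main clustering and so are not independent of it. Of 9 lists at least 1.3-fold apart, 1 value of 99 was reversed in settings planned beforehand and 0 of 36 in added ones. Of the values of 153 other named genes, 1 of 1376 planned and 4 of 612 added values were counted as reversed. These totals include genes less than 1.3-fold apart, whose sign changes were not counted. No paired analysis was possible because each group has 1 library. Depth limits genes such as *Timd4*, with 36 and 11 UMIs.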

Other observations

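Of the tests below only the thinning of the Trem2 genes was chosen before the data were examined; the subtraction of background and the tests of neutrophil transcripts were chosen after. Among other cells of the gate, dendritic-like cells (300 barcodes in WT and 270 in the library labelled CD40 KO) had *Ccr7*, a receptor of migrating dendritic cells, at 160 and 245 CPM and *Cd209a*, a marker of conventional type 2 dendritic cells, at 150 and 88.5 CPM. They had more *Cd40* than macrophage-like cells in both libraries. Fibroblast-like cells (130 and 87 barcodes) had *Col1a1* at 4069 and 4065 CPM. Endothelial-like cells numbered 205 and 12.

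Both libraries had Y-linked transcripts, *Ddx3y* at 69.7 and 82.4 CPM, and nearly no *Xist*, at 0 and 0.021 CPM. In cluster 3, *Ly6c2* stood at 164 and 262 CPM and *Ccr2*, the receptor that recruits monocytes, at 285 and 223 CPM.

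The Trem2 and lipid-associated list, with a median of −0.84, was weighed against free RNA and depth. The median was −0.91 once the background profile was subtracted. This covers only free RNA of that profile at its estimated share, 6.31% of UMIs, which is too small to move the median far. With every barcode thinned to the same UMIs the median was −0.88. Thinning evens the weights of barcodes but leaves the expected CPM of each unchanged, so it cannot decide on depth. With cluster shares made equal the median was −0.50, but cluster 1 is led by genes of this list, so that value does not separate its share from its expression. Whether the CD40 genotype accounts for it cannot be told apart from any other difference between the libraries, such as mice, surgery or sorting, with 1 library per group. It stays open.

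In cluster 7, macrophage-like cells held neutrophil transcripts, above the level of the class, at 0.823 and 0.788 times the UMIs of a neutrophil-like barcode, over 13 neutrophil genes, 5 of which reached 10 CPM in the WT class. Its barcodes in WT were deeper than the class (median 20061 against 11691 UMIs) with a higher median doublet score (0.136 against 0.094), as doublets would be. Chance pairs as the whole cause are argued against: before doublet removal WT had 1132 such barcodes, 18.1 times the number random pairs would give. The expected number rests on the 302 neutrophil-like barcodes kept in WT. It may be too low, since 1547 WT barcodes missed the UMI or gene minimum. *S100a8* plus *S100a9* were 64.4 times the level of the rest of the class. Free RNA spread evenly over barcodes would not give this, but part of the gap is built in, because neutrophil genes set cluster 7 apart. The cluster may follow the neutrophils present, since its barcodes per neutrophil-like barcode were 2.93 in WT and 2.75 in the library labelled CD40 KO, a log2 ratio of −0.092 (−0.33 to 0.14), although the CD64 gate would remove most free neutrophils. That interval takes the 302 and 64 neutrophil-like barcodes as fixed, so it leaves out their counting error and is too narrow. The neutrophil-like counts also carry the unequal depth limits of the libraries. Whether these are engulfed neutrophils or cells that stuck together stays open.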
